A study of Mus musculus with 7 samples.

How the data were processed

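RNA from 7 mouse cell lines had been hybridized to Illumina bead arrays as biotin-labelled cRNA in 1 colour, with 1 array per line. The 6 epiblast stem cell lines (OG2.1, OG2.2, E3, E5, T9 and C1a1) formed one group, and the embryonic stem cell line R1 stood alone. No line was sampled again, so lines served as the replicates of the EpiSC group.

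The deposited intensity values were bead-summarised probe signals on a linear scale, exported from BeadStudio 3.2 per the labels and neither normalized nor background subtracted. The deposited detection p-value of each probe compared it, per the file headers, with the negative control beads of the same array. The authors also deposited log2 values that had been quantile normalized between the 7 arrays. BeadStudio 3.2, lumi and RMA are named in the submitters' processing notes, and their order and settings are not given in the sources used here. Median signals ran from 123.5 (E3) to 131.3 (T9), and the share of the 25697 probes above background from 41.4% to 45.0%. The number of arrays limits the precision. Each deposited log2 column was checked against the signal of its own array (r of deviations from the probe mean at least 0.820, against at most 0.233 with other arrays).

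Intensities were normalized with neqc in limma 3.58.1, which fits a normal-exponential background from the detection p-values, adds an offset of 16 and applies quantile normalization on the log2 scale. Probes with a detection p under 0.01 on at least 1 array were kept, 13396 in all. The array's probe table gave 1 gene symbol for 23978 probes and no gene for 1719, and 12626 kept probes had a symbol. The reference gene table served for gene names only. The brightest probe represented each gene, which left 9213 genes, 2435 of them with more than 1 kept probe. Among the called genes, 348 had more than 1 kept probe, and 0 had another probe called in the opposite direction by limma. Of kept probes with no gene listed, 121 passed the EpiSC and ESC comparison and were not followed further.

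Limma was fitted to all genes, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. EpiSC minus ESC had 5 residual degrees of freedom, all from the EpiSC lines, and could not separate cell type from the R1 line or its array. Each line minus the mean of the other 5 had 4, with its own adjustment, and could not separate a line from its array. On simulated data with 200 of 9213 genes changed, the first comparison recovered 0% of log2 changes of 1, 70.5% of 2 and 99% of 4, with 0, 8 and 13 false calls. The comparison of a line with the other 5 recovered 0%, 62% and 97.5%, with 0, 8 and 10 false calls. The changed genes were drawn at random and given independent noise, so these shares do not describe genes that vary widely between lines. In the data, Hoxc6 in OG2.2 (4.73) and Fgf8 in E5 (-4.50) were not called.

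Gene lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined. Of 30 lists, 29 had at least 5 tested members, and 452 of 512 entries were matched to the array, 15 through an older symbol. Some genes belonged to several lists, so the results of related lists were not independent. Lists were tested 2-sided with camera at a preset correlation of 0.01 between genes and again with an estimated one. Adjustment was over 29 lists for the cell types and over 174 list and line combinations for the lines. The median SD of a list over the 6 lines was ranked among 10000 random lists matched on mean expression in 20 bins. The mean and SD of the negative control beads were taken as limma infers them from the detection p-values. Correlations of list means over the lines used exact 2-sided permutation of all pairings.

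The text names the 10 largest increases and 10 largest decreases among called genes between cell types, and up to 3 of each per line. It also names the 25 genes of a marker panel and, for each list described, up to 4 members with the largest differences either way. Hba-x, Azin2, Kdm5d, Lce3b, Ccl27a, Uty, the fibroblast genes given for single lines and the OG2.2 genes found without OG2.1 fall outside this rule and were chosen after their values were seen. The panel genes T, H19, Meg3 and Ddx3y had no probe listed under those names, and Sox1 and Pax6 were not above background on any array. Where a gene was below background throughout one side of a comparison, a fold is a lower bound. It was computed against the lowest normalized value among detected probes of each array, or the probe's own value if higher.

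The alternatives chosen beforehand used the deposited log2 values, no background correction, median scaling, no detection filter, a detection p under 0.05, the mean of a gene's probes, every probe, a trended and robust variance, a size threshold of 1, the EpiSC arrays normalized alone and the removal of each line. A size rule with no test and the removal of OG2.1 together with OG2.2 were added after the data had been seen. A block for the slide was not run, because slide names are not given in the sources used here. Probe sequences were not used here either, so signal shared between related genes was not examined.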

Results

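Gene expression was measured in 7 mouse pluripotent cell lines on Illumina bead arrays, with 1 array per line. Epiblast stem cells (EpiSCs) are pluripotent lines with the character of the epiblast after implantation, whereas embryonic stem cells (ESCs) stand closer to the epiblast of the blastocyst. The EpiSC lines were OG2.1, OG2.2, E3, E5, T9 and C1a1, and the ESC line was R1. The array carried 25697 probes, of which 10642 on E5 to 11574 on C1a1 lay above the array's own background, with 10670 on R1. Of 9213 genes tested, 7391 in E5 to 8058 in C1a1 were above background. Each line was sampled once, so the p-values measure the spread between lines, culture and array differences included, and the number of arrays limits the precision.

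The first comparison asked how the EpiSC lines differed from the ESC line. Most genes of the naive, blastocyst-like state were lower in the EpiSC lines than in R1, 13 of 17 past the test. Dppa5a, an RNA-binding protein gene of ESCs, fell by 8.60 on the log2 scale (SE 0.43; EpiSC mean 6.04 ± 0.45, SD, n = 6, against 14.64 in R1). Zfp42, which encodes the ESC marker Rex1, fell by 7.87 (SE 0.52), and the nuclear receptor gene Esrrb fell by 7.63 (SE 0.51). Fgf5, a growth factor gene switched on in the epiblast after implantation, was at 10.09 ± 0.46 (SD, n = 6) in EpiSCs and not above background in R1, at least 21.1-fold higher. Dnmt3b, a de novo DNA methyltransferase gene, was higher by 2.49 (SE 0.25), and Pou5f1, the Oct4 gene that marks both cell types, differed by -0.06 (SE 0.48, adjusted p = 0.946).

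Limma called 1401 of 9213 genes at an adjusted p under 0.05, 654 of them higher and 747 lower in EpiSCs, and 1311 of them differed by at least 1 on the log2 scale. The largest fitted increases were in Chst1, a sulfotransferase gene (7.53, SE 0.37, at least 75.4-fold), Fgf5 (5.68, SE 0.44), the epithelial splicing regulator Esrp1 (5.32, SE 0.29, at least 35.1-fold) and Zfp608 (5.24, SE 0.28, at least 19.1-fold). Cldn6, a tight junction claudin, was higher by 5.15 (SE 0.33), the ephrin receptor Epha1 by 5.09 (SE 0.43, at least 18.4-fold) and Cd59a by 4.82 (SE 1.09). The kinase gene Pim2, the carbonic anhydrase Car14 and Lbh completed the 10 largest fitted increases, at 4.69, 4.67 and 4.61. Pim2 and Lbh were not above background in R1, so they were at least 14.5-fold and 15.2-fold higher. On the other side stood Aard (-7.98, SE 0.82), Gstp2 (-7.36, SE 0.21, at least 88.6-fold lower) and Dppa4 (-7.06, SE 0.93). Dnmt3l, the cofactor of the de novo methyltransferases, followed at -6.95 (SE 0.84). The oocyte and embryo gene Ooep (-6.87), Rbmxl2 (-6.71) and the water channel Aqp3 (-6.66) were above background in R1 and in none of the 6 EpiSC lines, at least 68.2-fold, 50.1-fold and 66.3-fold lower. Adjusted p-values of these 20 genes ran up to 0.0212, the value for Cd59a, whose call ended without OG2.1 and OG2.2 (4.48, adjusted p = 0.0513). R1 was the only ESC line, so a difference between cell types could not be separated from the R1 line, its culture or its array. The single R1 array was assumed to vary like the EpiSC lines, and log2 values with an added offset understate the fold of dim genes.

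Among the gene lists fixed beforehand, 8 of 29 passed camera, a test of a list against all other genes, 4 higher and 4 lower in EpiSCs, and 2 of them passed with a correlation between genes estimated from the data. The naive pluripotency list was the most different: 13 of its 17 tested members fell, 14 when p was adjusted over the list alone, and its median was -5.41, or -5.15 with members below background at their bound. That call held with an estimated correlation (adjusted p = 0.0186). Klf4, a naive transcription factor gene, was lower by -5.67 (SE 0.33), and Dppa3 was above background only in R1, at least 2.80-fold lower in EpiSCs. The array held 20 listed naive genes, and those above background on no array were not tested. All 17 tested were above background in R1. Of these, 4 were above it in no EpiSC line and were tested only because of R1, which favours negative differences. Of the 5 tested germ cell genes, 4 fell, and all 5 did when p was adjusted over the list alone (list median -3.60, or -2.63 with bounds; adjusted p = 0.0489 with an estimated correlation). The array held 13 listed germ cell genes, and the others were above background on no array. All 5 were above background in R1, and 3 of them in R1 alone, which again favours negative differences. Dazl and Stra8, genes of germ cell development, lay above background in R1 alone, at log2 differences of -6.59 (SE 0.23, at least 49.2-fold) and -3.73 (SE 0.22, at least 6.19-fold).

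The epithelial list moved the other way, with 9 of 13 members higher in EpiSCs, 10 when p was adjusted over the list alone, Esrp1 and Cldn6 among them. Its median was 3.14, or 2.11 with bounds (adjusted p = 0.0660 with an estimated correlation). Of the 15 postimplantation epiblast genes, 7 were higher, 11 when p was adjusted over the list alone, and the median was 1.88, or 1.53 with bounds (adjusted p = 0.0660 with an estimated correlation). Fgf5 and Cldn6 belonged to this list, while Nodal stood at -1.96 (SE 1.13, adjusted p = 0.302). The glycolysis list split: 6 of 17 members were higher and 2 lower, or 8 and 2 when p was adjusted over the list alone, and its call was lost with an estimated correlation (adjusted p = 0.460). Aldoc, an aldolase, was higher by 4.05 (SE 0.38) and the lactate exporter Slc16a3, below background in R1, was at least 4.28-fold higher, whereas the hexokinase Hk1 was at -1.22 (SE 0.33) and the phosphofructokinase Pfkp at -3.03 (SE 0.51). Of 11 cholesterol synthesis genes, 3 were higher, 5 when p was adjusted over the list alone, among them Stard4 (1.97) and Cyp51 (1.28), with an adjusted p = 0.203 under an estimated correlation.

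Extraembryonic endoderm genes and mitochondrial respiration genes were the other lower lists. Of the 13 extraembryonic endoderm genes, 5 fell, 7 when p was adjusted over the list alone, with the basement membrane laminin Lama1 at -3.14 (SE 0.65). The list median was -1.48, or -1.24 with bounds (adjusted p = 0.203 with an estimated correlation). Of 30 oxidative phosphorylation genes, 3 fell, both over all genes and when p was adjusted over the list alone, and 24 had a negative difference. They included the cytochrome oxidase subunits Cox7a1 (-2.06, SE 0.29) and Cox5a (-0.97, SE 0.24), and the list's adjusted p = 0.0660 with an estimated correlation. Only the naive and germ cell lists passed with that estimate.

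**Figure D1:**
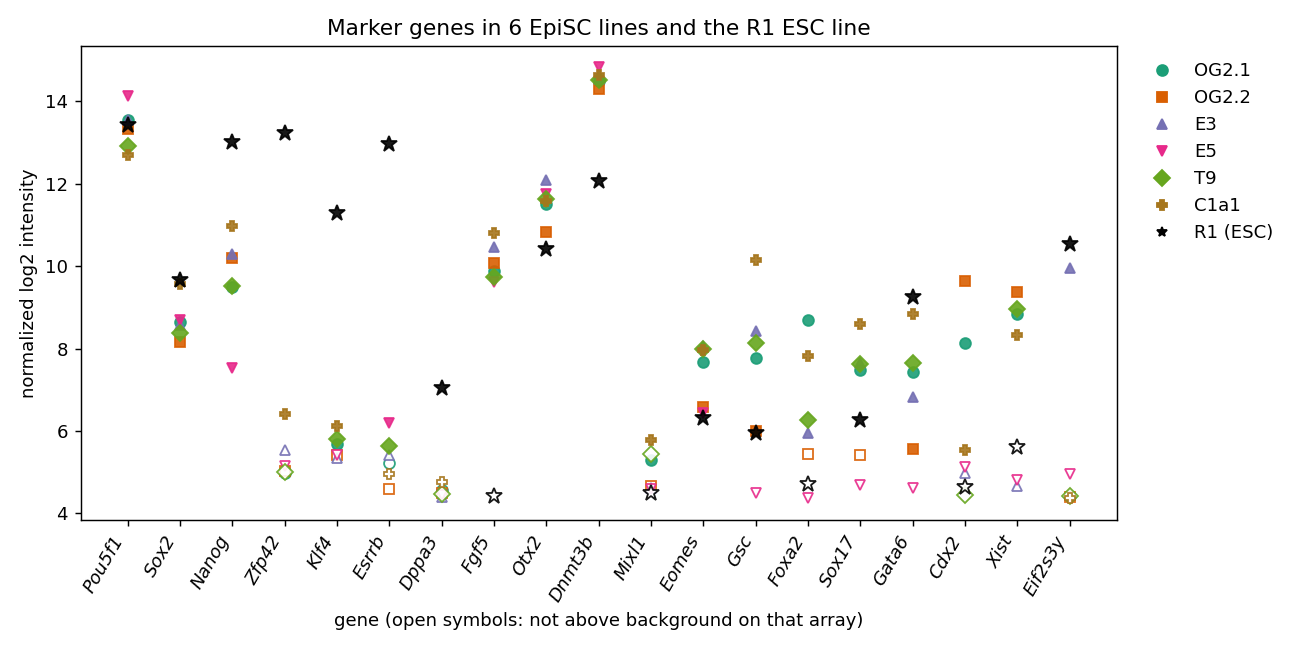
Normalized log2 intensity (vertical axis) of the 19 marker genes that could be tested, for the 6 EpiSC lines (coloured symbols) and the R1 ESC line (star), 1 array each; open symbols were not above background. Zfp42, Klf4 and Esrrb sat above 11 in R1 and below 7 in every EpiSC line, Fgf5 was above background in the 6 EpiSC lines alone, and Gsc, Foxa2 and Sox17 were lowest in E5.

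Genes of the first differentiation steps did not separate the cell types as a group. In the primitive streak and mesendoderm list, 13 of 16 members had a positive difference, whether or not they passed the test, and the median was 1.12. The list did not pass camera, and 0.42 was the median with members below background at their bound. Sp5 and Wnt8a, genes of Wnt signalling in the streak, were above background in 5 EpiSC lines and not in R1, at least 6.75-fold and 5.75-fold above it on average, and did not pass (adjusted p = 0.181 and 0.237). Lefty2, a Nodal antagonist gene, fell by 4.86 (SE 1.00, adjusted p = 0.0144). The streak and endoderm transcription factor genes Eomes (1.14), Gsc (1.53), Foxa2 (1.70) and Sox17 (0.63) did not pass singly, nor did Mixl1 (0.56), Cdx2 (1.66) or Gata6 (-2.42). Foxa2, Mixl1 and Cdx2 were not above background in R1, so their differences are fitted values. Nestin, the neural progenitor filament gene Nes, was higher by 3.21 (SE 0.31), the only 1 of 8 neuroectoderm genes to pass. Sox2 (-0.996, adjusted p = 0.198), Nanog (-3.33, adjusted p = 0.0664) and Otx2 (1.15, adjusted p = 0.0967) stayed short of the threshold. Nanog passed without E5 (adjusted p = 0.0145), without C1a1 (0.0498) and without background correction (0.0484), Otx2 without OG2.2 (0.0288) and without OG2.1 and OG2.2 together (0.0361), and Sox2 without C1a1 (0.0356).

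Markers of other cells and of sex chromosomes varied between the lines too. Of 11 fibroblast and feeder genes, 2 were higher in EpiSCs, both over all genes and when p was adjusted over the list alone, including the surface marker Thy1 (2.54, SE 0.45), and the list did not pass (adjusted p = 0.0805). Xist, the transcript of the inactive X chromosome, was above background in OG2.1 (8.83), OG2.2 (9.36), T9 (8.97) and C1a1 (8.33) and not in E3, E5 or R1. The Y-linked gene Eif2s3y was above background in E3 (9.96) and R1 (10.54) and in no other line, while the Y-linked gene Uty was faintly above it in OG2.2 (5.90), E3 (5.88), C1a1 (5.96) and R1 (6.26). The Eif2s3y cell type difference of -5.12 (adjusted p = 0.118) passed only without E3 (-6.02, adjusted p = 1.11e-04). Mesoderm, p53 target, mesenchymal and ribosomal protein lists had a median, mean and camera direction that differed in sign, and none of them passed.

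The EpiSC lines resembled each other more than any of them resembled R1. Across genes, which are not independent replicates, Pearson's r between arrays ran from 0.937 for E5 with C1a1 to 0.973 for E3 with T9, and from 0.844 for OG2.1 to 0.872 for T9 against R1. E3 and T9 had 504 genes at least 1 apart on the log2 scale, E5 and C1a1 had 1308, and EpiSC lines differed from R1 at 2344 to 2743 genes. OG2.1 and OG2.2 were at r = 0.968 with 662 such genes.

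The series title concerns differences between EpiSC lines, so the spread of each gene list over the 6 lines was examined. The lists with the widest spread included definitive endoderm, Nodal, Hox and streak genes. The median SD of the definitive endoderm list was 1.496 against 0.37 for random lists of matched brightness, of the Nodal and activin list 1.23 against 0.33, of the Hox list 1.15 against 0.36 and of the primitive streak list 1.04 against 0.38. In all, 20 of 29 lists lay above the central 95% of 10000 random lists, and 8 of them lay at the 100th: the bone morphogenetic protein (BMP), definitive endoderm, Hox, imprinted, mesoderm, Nodal, streak and Wnt target lists. Of the 20, 12 lay above that limit in all 10 alternative settings run for the spread. These were the deposited values, no background correction, median scaling, no detection filter and the removal of each line. Ribosomal protein genes (percentile 45.6) and cell cycle genes (35.2) varied like other genes, and oxidative phosphorylation genes (0.08) varied less. Percentiles describe these 6 arrays and are not a test of conditions, and lists that share genes are not separate findings.

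**Figure D2:**
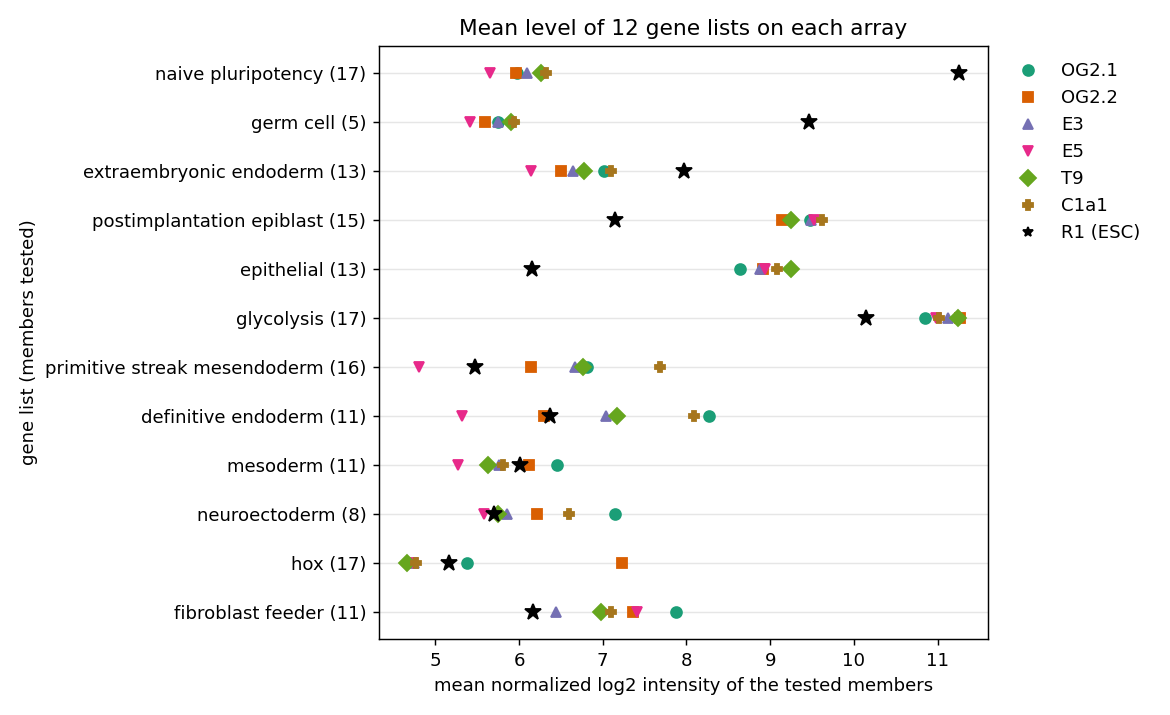
Mean normalized log2 intensity (horizontal axis) of the tested members of 12 gene lists on each array, with the 6 EpiSC lines as coloured symbols and R1 as a star; numbers in brackets are members tested. R1 stood apart for the naive list (11.26 against 5.65 to 6.32), E5 was lowest for the streak list at 4.81, and OG2.2 was highest for the Hox list at 7.23.

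Each line was then compared with the other 5. E5 stood out by what it lacked: only 1 of 16 streak genes, Eomes, was above background in E5, against 8 in OG2.2, 11 in OG2.1 and E3, 12 in T9, 14 in C1a1 and 5 in R1. Fgf8, a growth factor gene of the streak, and Sp5 were above background in all other 5 EpiSC lines and not in E5, at least 11.04-fold and 11.1-fold lower (log2 -4.50, SE 0.67, and -4.39, SE 0.70). The Nodal antagonist Lefty1 was likewise at least 21.2-fold lower (-4.44, SE 1.11), and the endoderm gene Hhex at least 6.27-fold lower (-2.77, SE 0.60). None of these genes passed over all genes (adjusted p = 0.228, 0.232, 0.438 and 0.350). Limma called 0 genes in E5, with 746 at an unadjusted p under 0.05.

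As lists, 8 were lower in E5 by camera with a preset correlation. Some of them share genes, such as Sp5 in the streak and Wnt target lists and Bmp4 in the mesoderm and BMP target lists, so they are not separate findings. The streak list had 15 of 16 members negative (median -1.44, or -0.83 with bounds; 3 lower when p was adjusted over the list alone), and the definitive endoderm list 11 of 11 (median -2.45, or -1.30 with bounds; 1 lower when p was adjusted over the list alone). The others were the mesoderm, Wnt target, Nodal, BMP target, mesenchymal and hypoxia lists, with medians of -0.67, -1.04, -0.74, -1.05, -0.66 and -0.63, or 0, -0.28, -0.32, -0.18, -0.61 and -0.35 with bounds. Adjusted over the list alone, 2 Wnt target, 2 Nodal and 1 BMP target genes passed, and 0 of the mesoderm, mesenchymal and hypoxia genes. Cholesterol synthesis was the 1 higher list (median 0.32), with Mvd at 1.07 and Fdps at 0.80, and 2 members passed when p was adjusted over the list alone. For all 9, the call was lost with an estimated correlation (adjusted p = 0.861 for each). Of the fibroblast and feeder genes, Dcn (9.30), Loxl1 (6.70), Thy1 (9.61) and Fstl1 (10.48) were highest in E5 among the 6 lines and 3 of 11 were lowest there.

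OG2.2 expressed Hox genes, the transcription factor genes of axial position, that the other EpiSC lines mostly lacked. Of 17 Hox genes tested, 16 were above background in OG2.2, against 6 in OG2.1, 1 in E5, 0 in E3, T9 and C1a1, and 5 in R1. The array held 22 listed Hox genes, and those above background on no array were not tested. Hoxa9, Hoxb1, Hoxb4, Hoxb6, Hoxb9, Hoxd4, Hoxd8 and Hoxd9 were above background on OG2.2 alone. They were tested only because of OG2.2, which favours positive differences there. Hoxc6 was at 9.77 against a mean of 5.04 ± 0.68 (SD, n = 5) in the other lines, a difference of 4.73 (SE 0.61), and Hoxc9 at 8.41 against 4.83 ± 0.56, a difference of 3.58 (SE 0.51). Cdx2, a caudal-type gene, was at 9.63 in OG2.2 and 8.13 in OG2.1. All 17 members were positive, with a median of 2.64, or 1.82 with bounds, and 16 passed when p was adjusted over the list alone, but 0 passed over all genes. The list passed camera with a preset correlation and not with an estimated one (adjusted p = 0.861).

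Limma called 0 genes in OG2.2, with 487 at an unadjusted p under 0.05, and 14 genes without OG2.1, the line with the next highest Hox list mean (5.38). Of those 14, 9 were Hox genes, led by Hoxc6 (5.01) and Hoxc9 (3.81), and the others were Npy, Cdx2, H2aj, Casp9 and Thumpd1, named after their values were seen. Hypoxia genes were also higher in OG2.2, 10 of 10 positive (median 1.08, or 0.93 with bounds) with 5 passing when p was adjusted over the list alone, including Ndrg1 (2.23) and Adm (2.097). P53 target genes were higher with a median of 0.37, led by Bbc3 (0.98) and Cdkn1a (0.93), and 0 passed over the list alone. Both list calls were lost with an estimated correlation (adjusted p = 0.861 for each). Mmp2 (10.55) and Col1a1 (5.99), 2 of 11 fibroblast and feeder genes, were highest in OG2.2. Among the genes called without OG2.1, Casp9 (-4.13) and Thumpd1 (-6.41) were lower in OG2.2. They were at 5.01 and 4.60 there and at 4.76 and 4.49 in OG2.1. Npy was high in both lines, at 11.25 in OG2.2 and 10.05 in OG2.1.

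**Figure D3:**
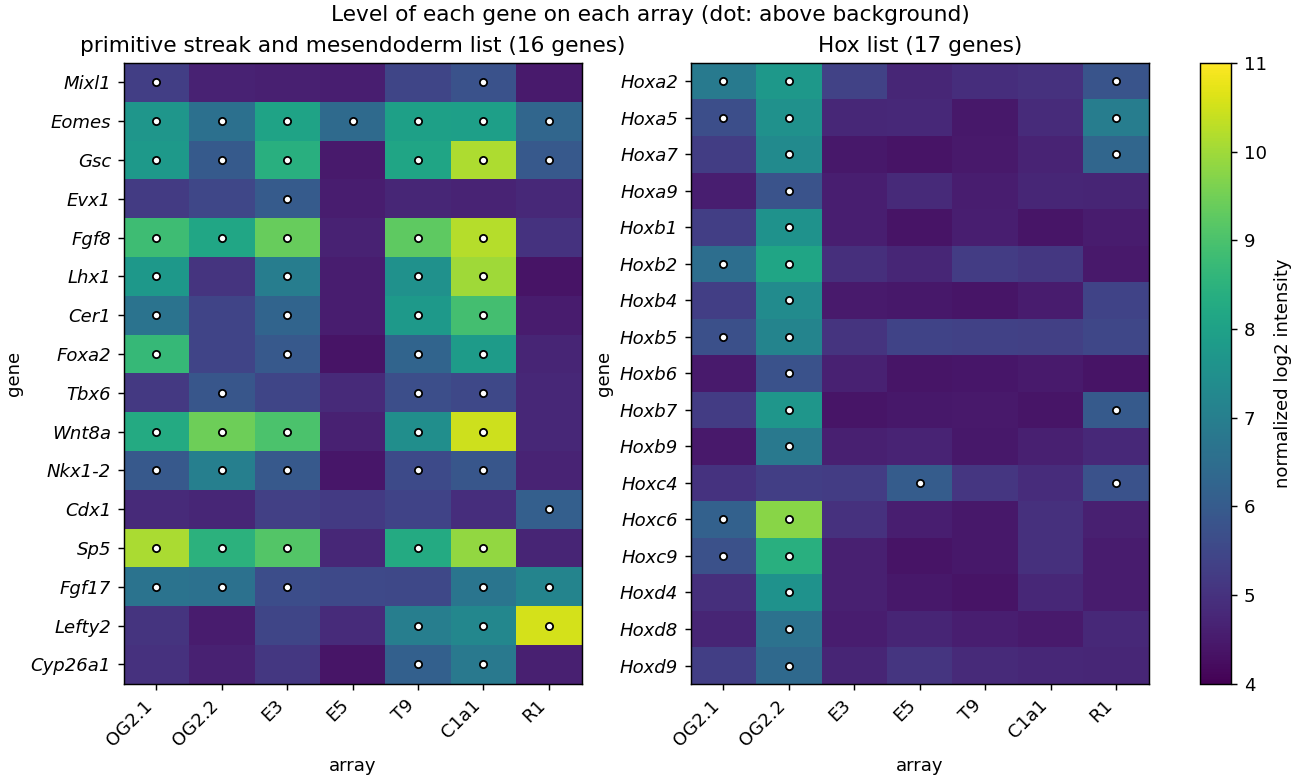
Normalized log2 intensity (colour scale) of the 16 streak and mesendoderm genes and the 17 Hox genes tested, by gene (vertical) and array (horizontal), with a dot where a gene was above background. E5 had a dot for 1 streak gene and C1a1 for 14, and OG2.2 had a dot for 16 Hox genes.

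OG2.1 was marked by embryonic globins. Hbb-y, the epsilon-type globin of primitive red cells, was at 8.25 in OG2.1 and below background in the other 5 lines and R1, at least 6.50-fold higher (log2 3.76, SE 0.23, adjusted p = 0.00601). Hbb-bh1 (3.51, SE 0.25, at least 5.88-fold) and Hba-x (2.45, SE 0.25, adjusted p = 0.0497, at least 2.76-fold) were likewise above background in OG2.1 alone, as was Scara3, a scavenger receptor gene (3.44, SE 0.32, at least 6.01-fold). These 4 genes were all that limma called, and leaving out E3 or E5 reduced them to 1.

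With a preset correlation, 7 lists were higher in OG2.1 and none lower. Some share genes, such as Gata2 in the mesoderm and BMP target lists and Twist1 in the mesoderm and mesenchymal lists. Definitive endoderm genes had 11 of 11 members positive (median 1.42), with Shh, a signalling ligand, at 4.08 (SE 1.58) and Foxa1 at 2.75 (SE 0.94). Neuroectoderm genes had 8 of 8 (median 0.69, or 0.48 with bounds), led by Sox21 at 4.04 (SE 1.65), and mesoderm genes 9 of 11 (median 0.80, or 0.56 with bounds), led by Gata2 (at least 2.51-fold, adjusted p = 0.0896) and Twist1 (2.09). The mesenchymal (median 1.15, or 0.86 with bounds), BMP target (0.85), Wnt target (0.76) and fibroblast and feeder (0.86) lists were the others, and the feeder list included Dcn (2.67) and smooth muscle actin, Acta2 (1.995). Adjusted over the list alone, the counts were 3 for mesoderm, 2 for mesenchymal, 2 for BMP targets, 1 for Wnt targets, 1 for neuroectoderm and 0 for definitive endoderm and feeder genes. Each of the 7 calls was lost with an estimated correlation (adjusted p = 0.861 for each), and those of the definitive endoderm (0.0600) and Wnt target (0.135) lists also without the detection filter.

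C1a1 had the highest streak levels of the 6 lines. Its streak list mean was 7.69 against 4.81 to 6.81 in the others, with 14 of 16 members positive (median 1.70), and the organizer genes Lhx1 (3.64, SE 1.23) and Gsc (3.18, SE 1.404) led it. Definitive endoderm genes had 10 of 11 members positive (median 1.69), with Cer1 at 2.77 and Gata6 at 2.41, while Trh was at -2.21. Interferon response genes were higher too (median 0.89, or 0.75 with bounds), 3 of them when p was adjusted over the list alone, with Oasl2 at 1.53 and the immunoproteasome subunit Psmb8 at least 1.63-fold higher. The 3 calls were lost with an estimated correlation (adjusted p = 0.861 for the streak and interferon lists and 0.890 for definitive endoderm), and 0 streak or endoderm genes passed over the list alone.

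The genes called in C1a1 included 1 interferon-induced gene, Gbp3. Xlr4a, an X-linked gene of a multicopy family read here by its brightest probe, was at 11.84 in C1a1 and 12.24 in R1 against a mean of 5.68 ± 0.56 (SD, n = 5) in the other lines, a difference of 6.16 (SE 0.52, adjusted p = 0.0352). Gbp3, which encodes a GTPase, was higher by 2.48 (SE 0.25, at least 4.19-fold). The mitotic kinase gene Plk1 was lower at -4.24 (SE 0.44), as were the membrane protease St14 at -3.44 (SE 0.33, at least 5.25-fold), the proteasome subunit Psmd8 at -2.82 (SE 0.25; 7.58 in C1a1 and 7.53 in R1) and the chemokine Ccl27a at -2.70 (SE 0.23). Limma called these 6 genes, and 0 when OG2.1, OG2.2, E3, E5 or T9 was left out.

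E3 alone among the EpiSC lines had the Y-linked genes Eif2s3y and Kdm5d above background. Uty was faintly above it in E3, OG2.2 and C1a1, but differed little between the EpiSC lines, from 5.37 in T9 to 5.96 in C1a1, and did not set E3 (5.88) apart. Eif2s3y was higher (log2 5.44 above the other lines, SE 0.29, at least 21.1-fold), as was Kdm5d (2.40, SE 0.23, at least 2.72-fold). The peptide transporter Slc15a2 (3.29, SE 0.21, adjusted p = 0.00641, at least 4.61-fold), Tmie (3.76, SE 0.29, at least 8.20-fold), Azin2 (at least 5.64-fold) and Lce3b (at least 2.32-fold) completed the 6 genes called, all above background in E3 alone among the EpiSC lines. Fibroblast and feeder genes were lower in E3, with 11 of 11 negative (median -0.79, or -0.36 with bounds), including Dcn, at least 3.04-fold lower. Mesenchymal genes were lower with 11 of 12 negative (median -0.58, or -0.55 with bounds), including Zeb1 and Zeb2, at least 2.41-fold and 2.35-fold lower. No member of either list passed over the list alone, and both calls were lost with an estimated correlation (adjusted p = 0.861 for each). The gene count was 2 without OG2.1 or C1a1 and 3 without OG2.2, E5 or T9.

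T9 was closest to the other lines on average (mean r of 0.963). Its 1 called gene was Nckap1l, a gene of blood cell actin regulation, at 9.85 in T9 and 8.17 in R1 and not above background in the other 5 lines, at least 19.5-fold higher (log2 4.58, SE 0.32, adjusted p = 0.0141). Stress response genes were higher in T9 (median 0.60), led by the integrated stress response genes Chac1 (3.08, SE 1.32) and Trib3 (1.80, SE 0.83). The stress list mean was nearly as high in E5, at 9.44 against 9.47 in T9, with Chac1 at 11.47 and Trib3 at 7.33 in E5. The neuroectoderm and Hox lists were lower (medians -0.45 and -0.65), but 0 with bounds for both. The Hox mean of T9 (4.66) was close to those of E5 (4.73), E3 (4.75) and C1a1 (4.77), with OG2.1 and OG2.2 above them, and the neuroectoderm mean was lower in E5 (5.59) than in T9 (5.75). The 3 calls were lost with an estimated correlation (adjusted p = 0.861 for stress response and neuroectoderm and 0.958 for Hox), and 0 members passed over the list alone. The gene count was 0 without OG2.1, OG2.2 or C1a1 and 2 without E3.

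Across the 6 lines, the mean of the streak list was compared with those of 4 other lists. It rose with the naive pluripotency mean (Pearson's r = 0.923, exact permutation p = 0.00972, adjusted p = 0.0389 over the 4), although Spearman's rho was 0.829 (exact permutation p = 0.0583, adjusted p = 0.233). Without E5 and C1a1, the lines farthest from the median, r was 0.494, so the relation rests on those lines. The call was also lost without background correction (exact permutation, adjusted p = 0.133), where r itself was 0.932. Between 7 and 10 of the 17 naive genes were above background in an EpiSC line. The naive means spanned 5.65 in E5 to 6.32 in C1a1, far under the 11.26 of R1. Against neuroectoderm r was 0.569 (exact permutation p = 0.239, adjusted p = 0.478; rho 0.714, p = 0.136), against postimplantation epiblast 0.167 (p = 0.744, adjusted p = 0.744; rho 0.257, p = 0.658) and against fibroblast and feeder genes -0.226 (p = 0.672, adjusted p = 0.744; rho -0.0857, p = 0.919). Without those lines r was 0.159, 0.739 and -0.0505.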

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

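The tests of feeder fibroblasts in E5, of less differentiation of every kind in E5 and of noise behind the OG2.1 globins were chosen only after the result was seen. A line was singled out when its gap to the nearest other line, divided by the range of the 6 lines, exceeded Dixon's 95% critical value for 6 samples. This held for 14 of 72 items tested, where chance gives about 1 in 20, or 3.6. Genes named for a line had been chosen because that line stood apart, so most of these results follow from that choice.

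In OG2.1 the ratios were 0.955 for Hbb-y (8.25, next line 4.57), 0.8998 for Hbb-bh1 (8.11, next 4.76) and 0.813 for Scara3 (8.14, next 5.16). In E3 they were 0.895 for Eif2s3y (9.96, next 4.95), 0.860 for Tmie (8.59, next 5.12) and 0.955 for Slc15a2 (7.76, next 4.54). In T9 the ratio was 0.867 for Nckap1l (9.85, next 5.53). C1a1 was highest at Xlr4a (0.811; 11.84, next 6.43) and Gbp3 (0.844; 7.66, next 5.39). C1a1 was lowest at Psmd8 (0.867; 7.58, next 10.22), St14 (0.804; 4.34, next 7.33) and Plk1 (0.746; 6.61, next 10.25). No other cell cycle gene on its list fell as far as Plk1 in C1a1: the next lowest relative to the other lines was Mcm3 at -0.74. The mean of the Hox list stood apart in OG2.2 (0.721; 7.23, next 5.38), and the mean of the cholesterol synthesis list in C1a1 (0.658; 10.09, next 10.54). Insig1 (-4.35) and Idi1 (-1.72) were the lowest members there relative to the other lines, whereas 5 of 11, including Hmgcs1 (0.23) and Stard4 (0.21), were positive.

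Primitive streak genes were low in E5, where Fgf8, Sp5 and 13 of the other members were below the mean of the other lines. The list's median lay at percentile 0 of random lists of matched brightness. That rank was favoured, because the list was taken up for these same low values and varied more between lines than matched lists (median SD 1.04 against 0.38). It therefore cannot decide whether a weak E5 array was the whole cause. The median signal of E5 (125.9) lay between those of E3 (123.5) and T9 (131.3), while its share of probes above background was the lowest (41.4%). Fewer feeder fibroblasts in E5 could not be told apart: 3 of 11 fibroblast genes were lowest in E5 (exact 95% interval 6.02% to 60.97%), and 4 of 11, counted after the first count was seen, were highest there. The fibroblast list mean was 7.41 in E5, below OG2.1 (7.87) and above OG2.2 (7.36), C1a1 (7.10), T9 (6.98) and E3 (6.45). Less spontaneous differentiation of every kind in E5 could not be told apart either: 9 of 19 mesoderm and neuroectoderm genes were lowest in E5 (24.4% to 71.1%). Only 2 of 11 mesoderm and 2 of 8 neuroectoderm genes were above background in E5, so most values ranked there were below it. The median difference of both lists in E5 was 0 with bounds. A difference between the lines themselves stays open and was not tested.

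Hox genes were high in OG2.2, with Hoxc6 and Hoxc9 in front. The list's median lay at percentile 100 of matched random lists, a rank favoured by the Hox genes that were tested only because of OG2.2. Of all 22 listed Hox genes on the array, 16 were above background in OG2.2. That count does not depend on which genes were tested, and it argues against noise of dim probes on the OG2.2 array as the whole cause. Feeder fibroblasts in the OG2.2 culture remained open, with 2 of 11 fibroblast genes highest in OG2.2 (2.28% to 51.8%), although the fibroblast list mean was higher in OG2.1 (7.87) and E5 (7.41) than in OG2.2 (7.36) and Dcn was at 5.81 in OG2.2 against 8.99 and 9.30 there. A retinoic acid response in OG2.2 may be a candidate explanation and remained open too: 2 of 7 response genes, Crabp1 (8.41) and Crabp2 (8.84), were highest in OG2.2 (3.67% to 71.0%), and 3 were highest in OG2.1, namely Stra6, Meis1 and Meis2. The response genes Cyp26a1 (4.65) and Stra6 (4.46) were not above background in OG2.2. Cyp26a1 was highest in C1a1 (6.83) and Rarg in E5 (8.10). A difference between the lines themselves was not tested.

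Embryonic globins were seen in OG2.1. Only the 4 globins above background in an EpiSC line were examined. Hbb-y, Hbb-bh1 and Hba-x were above it in OG2.1 alone, which favours a count of 4 of 4 there. The size of the signals, rather than that count, argues against noise of dim probes on the OG2.1 array as the whole cause. They lay 12.2 to 30.3 SDs above the mean of that array's negative control beads, past a bound corrected over all probes. Hba-a1 alone passed that bound in OG2.2, E3 and T9. A minority of primitive erythroid cells in OG2.1 may be a source and remained open, as 1 of 7 erythroid genes, Lmo2 (7.47), was highest in OG2.1 (0.361% to 57.9%). Of the abundant erythroid genes, Car2 was at 9.36 and Tfrc at 10.32 in OG2.1, within the range of the other lines, and Blvrb at 9.51 was lowest there. A difference between the lines themselves was not tested.

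Setting R1 against the EpiSC lines called 1401 genes, and setting any EpiSC array against the other arrays called at most 3. R1 was thus the only 1 of 7 arrays to call as many, and 7 choices of a lone array are too few for a share under 0.05. When an EpiSC array was set alone, R1 was among the other arrays. It differed from each EpiSC line at 2344 to 2743 genes, which widened their spread. Fewer calls for an EpiSC array were therefore built in, and the contrast cannot decide the question.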

How the results depend on the processing

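The size rule and the removal of OG2.1 with OG2.2 were chosen after the data were seen. The EpiSC and ESC count was 1130 to 1469 genes in the settings chosen beforehand that count genes, 1899 probes when every probe was tested, and 1133 genes without OG2.1 and OG2.2. The share higher in EpiSCs was 46.7%, with 51.8% for deposited values, 41.3% without background correction and 42.7% without the filter. No named gene or list past its threshold reversed its direction where it was followed, while Pou5f1, near 0, ran from -0.22 to 0.07. Lists were followed at a preset correlation with deposited values, without background correction, with median scaling and without the detection filter, and not in the other settings. All 8 cell type lists passed in each of these, as did 17 of 27 line lists. With an estimated correlation 2 cell type lists and 0 line lists passed camera, where 6 line lists had an unadjusted p under 0.05. Line gene counts depended on the setting. Deposited values gave 1 for OG2.1, 1 for E3, 0 for T9 and 1 for C1a1. Without background correction they were 1 for OG2.1, 3 for E3 and 3 for C1a1. Without a detection filter OG2.1 had 12 and C1a1 2. OG2.1 had 7 with the mean of a gene's probes and 9 with every probe. The size rule gave 98 for OG2.1, 77 for OG2.2, 62 for E3, 144 for E5, 28 for T9 and 88 for C1a1. Leaving out 1 other line gave 1 to 4 for OG2.1, 0 to 14 for OG2.2, 2 to 3 for E3, 0 for E5, 0 to 2 for T9 and 0 for C1a1, each with fewer samples. Of 12 line genes followed, Hbb-y and Slc15a2 alone were called in all 13 alternatives. The cause of the other changes was not tested.

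With deposited values the Wnt target list in OG2.1 (adjusted p = 0.0560), p53 targets in OG2.2 (0.0549), the mesenchymal list in E3 (0.0563), cholesterol synthesis in E5 (0.0549) and definitive endoderm in C1a1 (0.0549) no longer passed. Without the detection filter, definitive endoderm (0.0600) and Wnt targets (0.135) in OG2.1, mesoderm (0.347) and hypoxia (0.0787) in E5, and neuroectoderm (0.200) and Hox (0.369) in T9 no longer passed. The streak and naive correlation was 0.932 without background correction (exact permutation, adjusted p = 0.133). The lowest r between EpiSC lines and the highest between an EpiSC line and R1 were 0.920 and 0.838 with deposited values, 0.951 and 0.898 without background correction and 0.966 and 0.932 without the filter. A gene below background has only a bound. No paired analysis was possible because the groups share no numbered pairs beyond the single R1 array.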

Other observations

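In C1a1, the imprinted growth regulator gene Cdkn1c, the imprinted gene Nnat and the sterol regulator gene Insig1 were not above background, whereas all other 5 EpiSC lines had them above it. Cdkn1c was at 5.13 in C1a1 against 10.91 ± 1.51 (SD, n = 5), at least 46.0-fold lower. Nnat was at 4.51 against 9.04 ± 1.12 (SD, n = 5), at least 12.7-fold lower, and Insig1 at 4.48 against 8.82 ± 0.90 (SD, n = 5), at least 10.9-fold lower. Phlda2, another imprinted gene, was at 11.56 in C1a1 against 9.76 ± 0.58 (SD, n = 5). None of these genes passed limma over all genes, and they were chosen after their values were seen.

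Among imprinted genes, Igf2 was higher in EpiSCs than in R1 by 4.48 (SE 1.27), short of the threshold (adjusted p = 0.0507). Of the trophoblast list, the keratin gene Krt8 was higher by 4.14 (SE 0.75) and the transcription factor gene Tfap2c lower by -5.14 (SE 0.43), while the list did not pass camera (adjusted p = 0.355). Egln3, a gene induced in hypoxia, was at least 7.34-fold higher, and the interferon-induced gene Bst2 was higher by 2.24 (SE 0.60). The medians of 225 X-linked genes lay between -0.08 and 0.09 in each line relative to the other EpiSC lines.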
